A study of Drosophila melanogaster with 6 samples.

How the data were processed

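The libraries were made with an Illumina TruSeq RNA kit from TRIzol-extracted total RNA of sorted cells, per the labels' protocols, which do not say whether the kit kept strand. Per the submitters' processing notes, the authors used FastQC 0.11.2, STAR 2.3.0e, SAMtools 0.1.19, HTSeq 0.6.1 and DESeq2 (no version given) with genome build dm6. The annotation release, the counting settings, any filter and whether ratios were shrunken are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, and near-identical gene copies can share or lose reads.

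The deposited table held 1 comparison over all libraries and no values per library. Per the file headers, the authors gave for each gene a mean over libraries of counts divided by size factors, a signal that is never negative. Per the file headers, the authors also gave a log2 ratio named with the control first, the standard error of that log2 ratio, a Wald statistic, a p-value and an adjusted p-value. The table was encoded in UTF-7 and was decoded before use. In each row the statistic was checked to equal the ratio over its standard error, with a largest difference of 9.77e-14, and the largest adjusted p was 0.0499, so only genes past the threshold were present. Multiplying each adjusted p by the rank of its p and dividing by the p gave 11859 as the number of genes behind the Benjamini-Hochberg adjustment, exactly (within 0.01) in 2883 rows. Size factors, totals and read depth per library are unknown, so the precision of each ratio is known only through the authors' standard error, which ranged from 0.06 to 0.79 with a median of 0.15.

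Samples were grouped by their titles into wild type and dom knockdown, 3 libraries each. Before the data were examined, the planned test was limma on log2 normalized values per library, with camera for gene lists, a replicate block, other scalings and each library left out in turn. None of these could be run without values per library, so the authors' DESeq2 comparison was used in their place, and the tests of gene lists and neighbouring genes described below were chosen after seeing the data. The threshold of 0.05, the lists themselves and the rule for named genes were fixed before. The sign of the ratio was taken from the header and from dom and w, and signs were turned to give knockdown over control. If the header order were the reverse, all directions would swap. Intervals are the ratio with 95% normal limits from the authors' standard error.

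Gene symbols came from a table that matched 3264 of 3326 IDs, and the other 62 IDs stayed unnamed, so counts within gene lists are minimums. Positions, biotypes and exon lengths came from Ensembl release 115 (BDGP6.54), the same assembly as dm6, and are 1-based. Of the 32 gene lists fixed before the data were examined, a list was tested for direction where at least 3 members were listed, which held for 22. The number of higher and lower members was compared with all other listed genes by a two-sided Fisher's exact test, adjusted over the 22 lists by Benjamini-Hochberg. An alternative set the members against 10000 permutation draws of listed genes matched on deciles of the mean normalized count, two-sided, with a smallest p of 1e-04. Another also matched exon length in 5 classes within each decile. The share of members listed was tested by a one-sided hypergeometric test in the 11859 genes over all 32 lists, with every member counted as tested. This test did not match abundance. Among listed genes the median standard error was 0.73 at a mean below 10 and 0.10 at 10000 or more. A larger share listed can therefore come from smaller errors at high counts. Genes within a list are not independent, so these p-values are approximate. In 29 of 32 lists the number passing was the same when adjusted over the list alone, with members not listed entered without evidence of change. The count fell in 3 lists, to 0 for replication and S phase, 0 for muscle markers and 1 for ribosome biogenesis.

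The scripts were tested on simulated data. In 5 runs of 12000 genes the number of tests was recovered exactly in 5, and of 500 lists without direction Fisher's exact test called 10 and the matched draws 12, while both called 500 of 500 lists of 10 higher genes. Those lists held no lower gene, so the call of Fisher's exact test on them was fixed in advance. Abundance classes were assigned at random in the simulation, so neither test was checked where direction follows abundance. Of 500 random lists the hypergeometric test called 31, and of 500 enriched lists 500. The test of neighbouring genes called 1 of 40 simulated sets of 300 genes placed at random among 1600, and 40 of 40 placed in clusters.

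The rule for named genes, fixed before the data were examined, took dom and the 15 largest ratios in each direction at a mean normalized count of at least 50. It also took up to 5 members per list with the smallest adjusted p (up to 3 by highest mean where fewer than 2 passed), and any member of the Tip60, apical polarity and neuroblast lists. Its requirement that the 3 knockdown libraries lie apart from the 3 controls could not be applied. Other genes were named after their values were seen: cv-2, Arc2, opa, Syt1, nrv3, ph-p, Hsp23, Hsp67Bc, Hsp70Ba and those of the closing section. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.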

Results

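RNA was sequenced from sorted cells of wandering Drosophila melanogaster larval brains. The insc-Gal4 driver, which is active in neuroblasts, the neural stem cells of the fly brain, labelled these cells and part of their progeny with membrane-bound GFP. Live GFP-positive cells were collected by flow cytometry. The knockdown genotype carried an additional hairpin transgene against domino (dom), which encodes the ATP-dependent nucleosome remodeller of the Tip60 complex. The wild type genotype came from a cross of the same driver line to w1118 males. Both genotypes carried a transgene for Dicer-2, an enzyme that strengthens RNA interference. There were 6 libraries, 3 wild type and 3 dom knockdown. Nothing in the labels says whether the sorts of one genotype came from separate batches of larvae, so the p-values may measure technical spread only. The values used here were those of the authors' comparison of the genotypes, which listed 3326 genes with an adjusted p below 0.05. Their mean normalized count over all libraries ranged from 4.47 to 700435 in the authors' deposited table, with a median of 1532. Read depth per library is unknown, because the table held no values per library.

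The question of the comparison was which transcripts of neuroblasts and their progeny depend on Domino. The target itself, dom (FBgn0020306, dm6 2R:21323430-21341847, plus strand, protein coding), was lower in the knockdown, at 0.671 times the control level in the authors' deposited table. Its log2 ratio in the authors' deposited table was -0.58 with a standard error of 0.11 and a DESeq2 adjusted p of 7.88e-07. The eye colour gene w, a shortened copy of which marks most fly transgenes, was 2.50-fold higher in the knockdown in the authors' deposited table (log2 1.32, SE 0.13), and Dcr-2, present as a transgene in both genotypes, was 1.87-fold higher (log2 0.90, SE 0.23). The column of ratios names the control first, and dom and w moved as they would in a ratio of control over knockdown. The signs were therefore turned here to give knockdown over control. Because dom helped to settle the sign, it does not also check the sample labels, and reads from the hairpin could add to its knockdown value.

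Arc1, which encodes a capsid-forming protein that carries mRNA across synapses, was 177-fold higher in the knockdown in the authors' deposited table, at a mean normalized count of 48486, and its neighbour Arc2 was 12.2-fold higher. Of the genes with a mean normalized count of at least 50, c-cup had the largest increase and CG18853 the largest decrease, with log2 ratios of 8.04 (SE 0.49) and -8.13 (SE 0.58) in the authors' deposited table. The homeodomain factor pros, which drives neural differentiation, had a mean normalized count of 375760 and was lower, at 0.291 times the control level (log2 -1.78, SE 0.27, DESeq2 adjusted p 6.65e-10 in the authors' deposited table). In total, 1646 genes were higher and 1680 lower in the knockdown, 49.5% and 50.5% of those listed. They were 28.0% of the 11859 genes behind the adjustment. Changes of at least 2-fold were mostly increases, with 757 genes higher and 239 lower, and the median log2 ratio was 0.91 among higher genes and -0.46 among lower genes. With all log2 ratios shifted by 0.1 up or down, in place of another centring, 59.9% or 41.7% of the genes still passing were higher, but genes outside the table have no ratio, so a shift can only remove genes from one side.

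**Figure D1:**
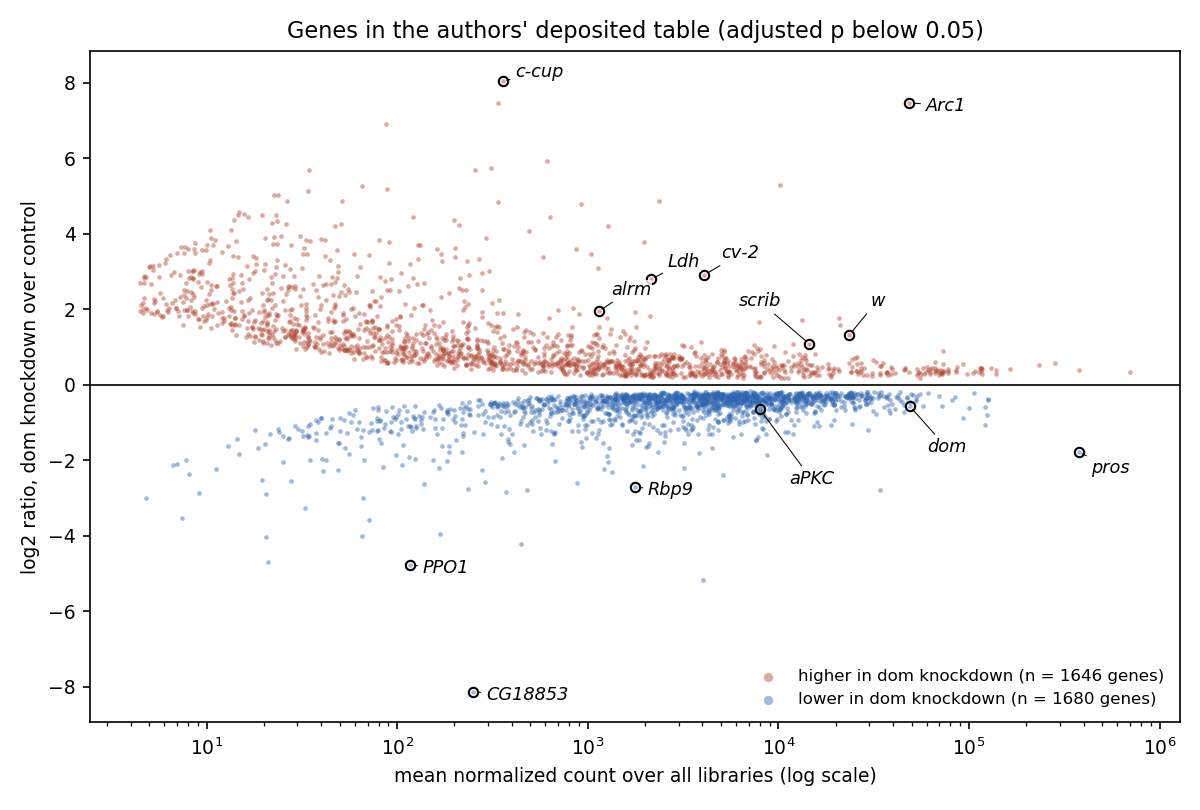
Each point is 1 gene of the authors' deposited table, with its mean normalized count over all libraries on a log-scaled horizontal axis and its log2 ratio of dom knockdown over control on the vertical axis. The 1646 higher genes reach larger ratios and lower counts than the 1680 lower genes, and dom lies at -0.58.

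Among the genes with the largest increases were CG3635, Gr59d, which encodes a gustatory receptor, the pseudogene CR33294, CG31664, CG15784 and ppk13, a member of the degenerin sodium channel family. Their log2 ratios in the authors' deposited table were 7.47 for CG3635, 6.91 for Gr59d, 5.92 for CR33294, 5.68 for CG31664, 5.28 for CG15784 and 5.18 for ppk13, with standard errors from 0.34 to 0.63. The noncoding RNAs lncRNA:CR45517, lncRNA:CR42646 and lncRNA:CR45973 were also in this group, with log2 ratios of 5.74, 4.86 and 4.80 in the authors' deposited table. CG3635, CG31664, CG15784, ppk13, Gr59d, lncRNA:CR45517 and lncRNA:CR42646 each lie at most 10 kb from another listed gene at least 4-fold higher, as do c-cup and Arc1. Whether differences between the parental lines caused such increases was not tested. The genes that fell most besides CG18853 were Culd (log2 -5.16, SE 0.19), the hemocyte enzyme gene PPO1 (log2 -4.77, SE 0.41) and IFT54 (log2 -4.22, SE 0.31), which encodes an intraflagellar transport protein, in the authors' deposited table. CG31683 and CG31636 followed at -4.02 and -3.96, the zinc finger gene dati fell by 2.78 and the intraflagellar transport gene nompB fell by 2.62 on the log2 scale in the authors' deposited table. The smallest adjusted p belonged to cv-2, a secreted modulator of BMP signalling chosen after its values were seen, which was 7.50-fold higher (log2 2.91, SE 0.10, DESeq2 adjusted p 1.13e-192 in the authors' deposited table). Values per library were not used here, so whether all 3 knockdown libraries lay apart from the controls was not examined for these genes.

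Most rare transcripts in the list were higher and most abundant ones lower. Of the 109 listed genes with a mean normalized count under 10, 93.6% were higher in the knockdown, and of the 373 with a mean from 10 to 50, 87.7% were. The share was 69.4% of 507 genes from 100 to 500, 44.5% of 649 genes from 500 to 2000, and 25.7% of 1004 genes from 2000 to 10000. Below 100, 581 of 679 genes were higher, against 424 of 1491 at 2000 or more (two-sided Fisher's exact test, p = 2.92e-144; genes are not independent replicates). Noncoding RNAs and pseudogenes followed their abundance: 170 of 219 listed ncRNA genes and 27 of 32 pseudogenes were higher, where permutation draws of listed genes of the same abundance gave 165 and 24.7.

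**Figure D2:**
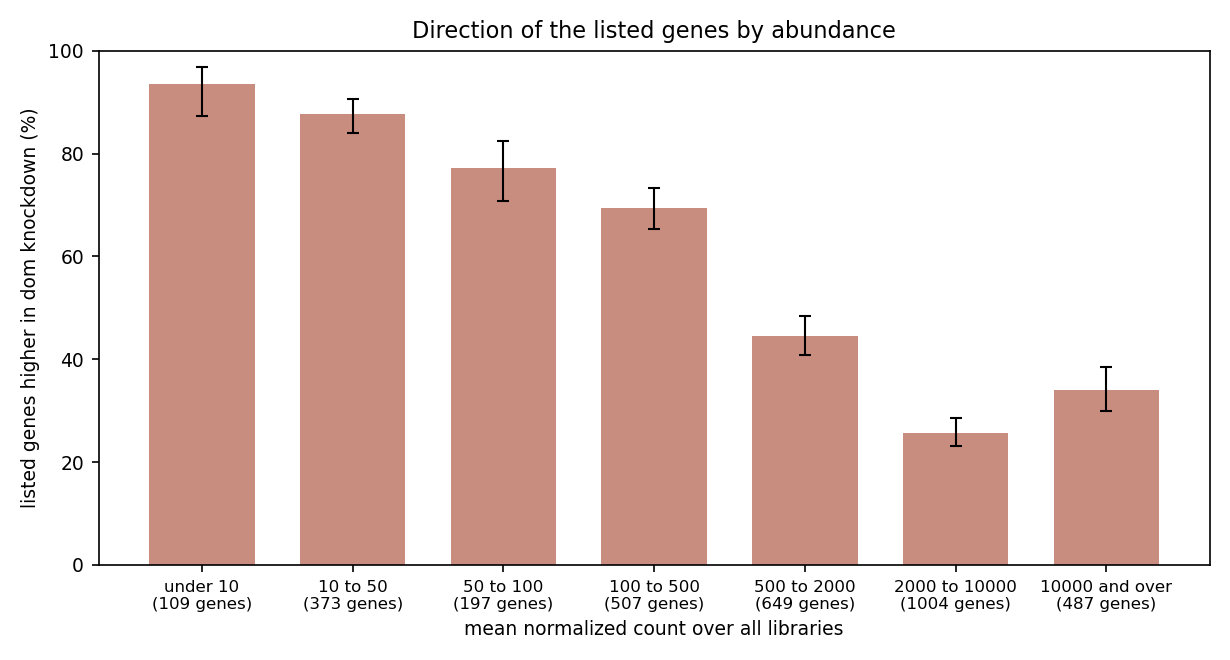
Bars show the percentage of listed genes that were higher in the dom knockdown, by class of mean normalized count over all libraries, with 95% Wilson intervals that cover counting error only. The percentage is 93.6 in the lowest class, 25.7 in the class from 2000 to 10000, and 34.1 in the highest class.

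Genes that polarize the dividing neuroblast changed in both directions. The apical kinase gene aPKC (2R:14944458-14962969) was lower, at 0.637 times the control level (log2 -0.65, SE 0.07, DESeq2 adjusted p 8.01e-18), and scrib, which encodes a cortical scaffold protein, was 2.12-fold higher (log2 1.08, SE 0.11, adjusted p 1.04e-21) in the authors' deposited table. The spindle orientation gene pins and the small GTPase gene Cdc42 were slightly lower, both at a log2 ratio of -0.22, and Galphai was higher at 0.50 (SE 0.20) in the authors' deposited table. In all, 5 of 16 genes for apical polarity and spindle orientation were listed, 2 higher and 3 lower, while baz, par-6, insc, mud, l(2)gl and dlg1 were among the 11 not listed. Among the basal determinants and their transport factors, 5 of 9 were listed: besides pros, the mRNA-binding protein gene stau was lower (log2 -0.44), and numb, an inhibitor of Notch, jar and sqh were higher (log2 0.52, 0.33 and 0.19) in the authors' deposited table. The direction of neither list differed from that of other listed genes (two-sided Fisher's exact test, adjusted p = 1.00 and 0.870).

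Of the 16 genes in the list for the Tip60 complex, which did not hold dom itself, 1 was listed. It was the histone variant gene His2Av, 1.52-fold higher in the knockdown in the authors' deposited table (log2 0.60, SE 0.15, DESeq2 adjusted p 7.08e-04). Tip60, Nipped-A, pont, rept, E(Pc) and MRG15 were among the 15 not listed. Of the Myc network, Myc was 1.39-fold higher in the authors' deposited table (log2 0.48, SE 0.15), with 61.2% of its exon bases shared with other annotated genes, and Max and Mnt were not listed. A gene that is not listed did not pass the threshold or was not tested, and its ratio is unknown.

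Listed genes of neural progenitors were mostly higher in the knockdown. The Snail family genes sna and wor, the cofactor gene nab and the Notch target E(spl)mgamma-HLH, all active in neuroblasts, had log2 ratios of 0.76 (SE 0.18), 0.61 (SE 0.23), 0.46 (SE 0.11) and 0.57 (SE 0.20) in the authors' deposited table, while grh was lower at -0.79 (SE 0.31). These were the 5 listed genes of 13 in the neuroblast list, and dpn, ase, mira and klu were not listed. Of 10 genes of type II lineages and intermediate progenitors, 6 were listed and all 6 were higher, with log2 ratios in the authors' deposited table of 0.81 for erm, 0.77 for tll, 0.67 for opa, 0.52 for D, 0.42 for fd59A and 0.40 for hbn. The gene tll is also in the list of optic lobe genes, and whether the increases were particular to type II lineages was not tested. Of 20 Notch pathway and E(spl) complex genes, 10 were listed, 9 of them higher, including E(spl)m7-HLH, E(spl)mbeta-HLH, E(spl)m8-HLH and E(spl)m6-BFM at log2 ratios of 0.81, 0.77, 0.74 and 0.71 in the authors' deposited table. The direction of these lists did not pass Fisher's exact test against all other listed genes (adjusted p = 0.0685 for the type II and the Notch list and 0.470 for the neuroblast list). Against permutation draws of listed genes of the same abundance, the adjusted p was 0.0029, 0.0011 and 0.0799. Several of the higher Notch list members lie in 1 gene cluster, from E(spl)mgamma-HLH to E(spl)m8-HLH (3R:25999851-26041008). The draws counted them as separate genes, so this p-value is too small if neighbours change together. The inhibitor gene numb was also among the 9 higher members.

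Temporal patterning genes and early differentiation genes did not share a direction. Among 13 temporal factors, svp and mamo were higher (log2 0.38 and 0.47) and Syp, EcR and grh were lower (log2 -0.40, -0.51 and -0.79) in the authors' deposited table, with 8 not listed, among them Imp and chinmo. Among 10 genes of ganglion mother cells and early neurons, the cell cycle inhibitor gene dap, nerfin-1 and tap were higher (log2 0.65, 0.45 and 0.38), and pros and sens-2 were lower (log2 -1.78 and -1.31) in the authors' deposited table. Of 16 genes of the optic lobe, 11 were listed, 7 higher and 4 lower, and this share was above that of all tested genes (hypergeometric test, adjusted p = 0.0134). The test did not match abundance, so the share may partly reflect smaller errors at high counts. The neuroblast temporal factor slp1 was higher (log2 0.78, SE 0.21), and hth, Rx and bsh were lower (log2 -0.94, -1.06 and -0.91, SE 0.17 to 0.20) in the authors' deposited table. With members below an adjusted p of 0.01 alone, the optic lobe list no longer passed (adjusted p = 0.0998). The direction of the temporal, ganglion mother cell and optic lobe lists did not pass Fisher's exact test (adjusted p = 1.00, 0.870 and 0.561).

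Listed markers of neurons were lower and listed markers of glia higher in the knockdown, beside the changes in progenitor genes. Of 20 neuron markers 7 were listed, all lower: Rbp9, a neuronal RNA-binding protein gene, at a log2 ratio of -2.71 (SE 0.15), fne at -0.87, the GABA synthesis gene Gad1 at -0.74, the synaptic vesicle gene Syt1 at -0.60, unc-13 at -0.57, cpx at -0.54 and nrv3 at -0.47 in the authors' deposited table. The markers elav, nSyb and brp were not listed. All 4 of 17 glia markers listed were higher, with log2 ratios in the authors' deposited table of 1.94 (SE 0.21) for the astrocyte gene alrm, 0.81 for htl, 0.72 for gcm and 0.56 for repo. Of 12 blood cell markers 4 were listed, all lower: PPO1 and PPO2, which encode the prophenoloxidases of crystal cells, at -4.77 and -1.51, Pxn at -1.19 and Hml at -0.80 in the authors' deposited table. None of these lists passed Fisher's exact test for direction (adjusted p = 0.0685, 0.220 and 0.305) or the abundance-matched permutation (adjusted p = 0.186, 0.0726 and 0.0799). Of other tissues, the fat body gene apolpp (1 of 8 listed), the muscle gene Act57B (1 of 12) and the proneural gene ato were higher, at log2 ratios of 1.14, 0.98 and 1.10, and the trachea factor gene trh (1 of 7) was lower at -0.76 in the authors' deposited table. With ato, nvy was the other listed member of the 13 imaginal disc and photoreceptor genes, at -0.58 in the authors' deposited table.

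**Figure D3:**
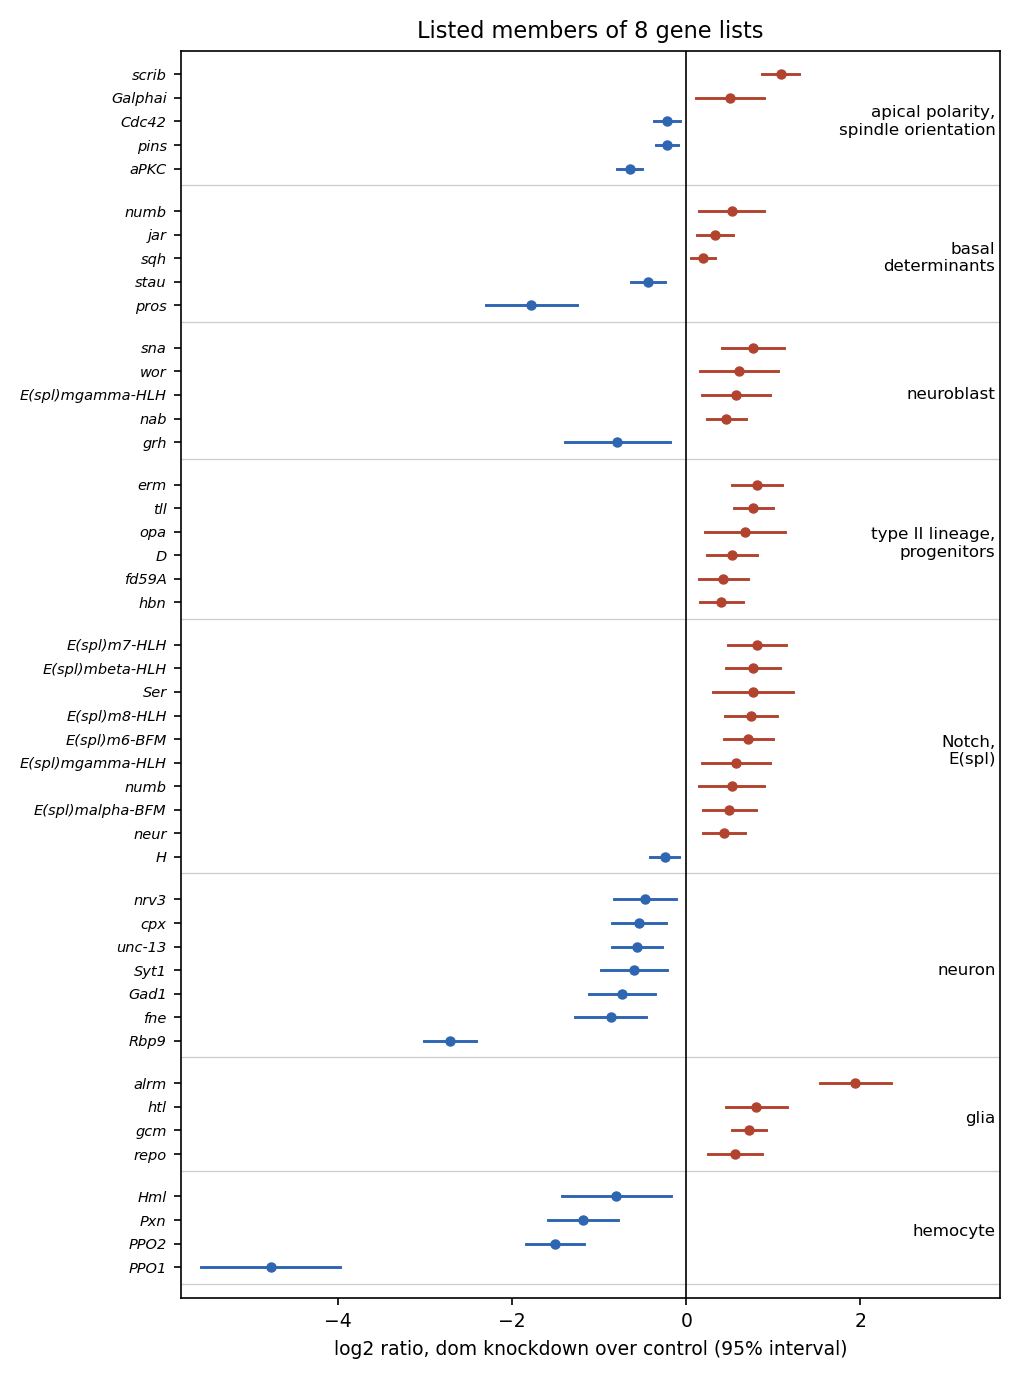
Points show the log2 ratio of dom knockdown over control from the authors' deposited table for the listed members of gene lists named at the right, and bars the 95% interval from the authors' standard error. All 7 listed neuron markers lie below 0, with Rbp9 at -2.71 apart from the rest, and all 4 listed glia markers and all 6 listed type II lineage genes lie above 0.

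All listed cytosolic ribosomal protein genes were higher in the knockdown. Of 93 such genes 48 were listed and higher, and 45 were not listed and have no known ratio. The 48 had a median log2 ratio of 0.35 (two-sided Fisher's exact test of direction, adjusted p = 3.36e-14; hypergeometric test of the share listed, adjusted p = 4.03e-05). The list also passed the abundance-matched permutation of direction (adjusted p = 0.0011), but the share listed was not matched on abundance. Short abundant genes were more often higher than long ones, and draws matched on exon length too, which include many ribosomal protein genes, gave 40.4 higher genes (permutation, adjusted p = 0.0022). Among other listed genes with a mean of at least 2000 and at most 1233 bp of exon, 51 of 94 were higher. The 45 with a mean normalized count of at least 1000 lay between 0.25 and 0.54, among them RpL15 at 0.54 (SE 0.10), RpS27 at 0.47 (SE 0.09) and RpS3A at 0.45 (SE 0.08) in the authors' deposited table. The low copies RpL37-2 and RpS10a had larger ratios, 4.36 and 2.83, at mean normalized counts of 13.9 and 48.7 in the authors' deposited table. Of 28 genes of ribosome biogenesis 3 were listed, all lower, namely Mybbp1A, pit and Polr1A at log2 ratios of -0.44, -0.32 and -0.30 in the authors' deposited table. When adjusted over the list alone, 1 of the 3 passed.

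Few cell cycle genes were listed. Of 24 genes of replication and S phase, PCNA and Mcm7 were higher (log2 0.73, SE 0.27, and 0.66, SE 0.23, in the authors' deposited table), and 22 were not listed. Neither passed when adjusted over the list alone, and 81.7% of the exon bases of Mcm7 were shared with an antisense gene. Of 28 mitotic genes, aurB was higher (log2 0.70) and twe and cal1 were lower (log2 -0.63 and -0.38) in the authors' deposited table. The genes CycA, CycB, Cdk1, stg and polo were among the 25 not listed. The standard errors of PCNA, Mcm7, aurB and twe were 0.27, 0.23, 0.23 and 0.17. Listed genes of their abundance had medians of 0.10, 0.11, 0.11 and 0.14. That of cal1 was smaller, 0.08 against 0.11. Members not listed have no known ratio, so the short list does not show that cell cycle genes were unchanged. In metabolism, Ldh, which encodes lactate dehydrogenase, was 6.91-fold higher (log2 2.79, SE 0.20, DESeq2 adjusted p 1.58e-43 in the authors' deposited table). The glycolytic genes Gapdh2 and Hex-A were also higher (log2 0.34 and 0.28 in the authors' deposited table), making 3 of 12 listed. Of 87 oxidative phosphorylation genes 9 were listed, 5 higher and 4 lower, with the largest ratios in the low copies COX4L and ATPsynepsilonL, at 3.12 and 2.82 in the authors' deposited table. The direction of the mitosis, ribosome biogenesis, glycolysis and oxidative phosphorylation lists did not pass Fisher's exact test (adjusted p = 1.00, 0.4997, 0.305 and 0.870).

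Most listed genes of other chromatin remodellers and of the Polycomb and Trithorax groups were lower. Of 27 such genes 12 were listed, 11 of them lower, among them Acf, Iswi, Chd1, Mi-2 and kis at log2 ratios of -0.66, -0.59, -0.52, -0.45 and -0.40 with standard errors from 0.06 to 0.15 in the authors' deposited table. The exception was ph-p, at 0.22 in the authors' deposited table. The direction of this list did not pass Fisher's exact test (adjusted p = 0.0685), nor the abundance-matched permutation (adjusted p = 0.127). Among the 8 Hox genes, which Polycomb and Trithorax proteins regulate, Ubx, Dfd, Scr and pb were lower (log2 -1.06, -0.59, -0.56 and -0.49) and Abd-B was higher (log2 0.73) in the authors' deposited table. Of 7 genes of the RNA interference machinery, vig, AGO1, loqs and Dcr-1 were lower (log2 -0.68, -0.42, -0.32 and -0.25 in the authors' deposited table) and Dcr-2, the gene with a transgene copy, was higher. Of the 5 transgene marker and driver genes, w and Dcr-2 were listed, and of 8 dosage compensation and sex genes, tra was lower (log2 -0.46 in the authors' deposited table). Direction did not pass Fisher's exact test for the Hox and RNA interference lists (adjusted p = 0.561 for both).

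Stress and damage response genes changed in both directions. The damage-responsive gene Gadd45 was 13.8-fold higher (log2 3.79, SE 0.24, DESeq2 adjusted p 2.18e-52), and the ligand gene egr, the transcription factor gene Xrp1 and p53 were higher at log2 ratios of 0.94, 0.82 and 0.65 in the authors' deposited table. Of the exon bases of p53, 38.02% were shared with an antisense gene. In the cell death and DNA damage list, 9 of 17 genes were listed, 6 higher and 3 lower. In the list of heat shock and immediate early genes 9 of 21 were listed, 5 higher and 4 lower. The immediate early genes sr and kay were higher (log2 0.97 and 0.50) and Hsp23, Hsp27 and Hsp67Bc were lower (log2 -0.81, -0.62 and -0.60) in the authors' deposited table. Hsp70Bb was higher and Hsp70Ba lower (log2 1.77 and -1.31 in the authors' deposited table), both uncertain because near-identical Hsp70 copies can share or lose reads, which was not examined. Of 26 immune genes, the NF-kappaB gene dl and AttB were higher (log2 1.41 and 0.76 in the authors' deposited table). Of 23 genes for adhesion and axon guidance 9 were listed, 7 higher and 2 lower, including NetA at 0.69, robo2 at 0.45, trn at 0.43 and Dscam1 at -0.74 in the authors' deposited table, with 41.04% of the exon bases of robo2 shared with other genes. Fisher's exact test for direction gave adjusted p = 0.561 for cell death, 0.870 for heat shock and 0.305 for adhesion, and for the adhesion list the abundance-matched permutation gave 0.0401.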

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

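All alternatives here were chosen after seeing the data. No paired analysis was possible because the deposited table holds no values per library, and for the same reason the planned pseudocounts, filters, scalings, limma, edgeR and camera settings, the left-out libraries and other splits of the 6 samples were not run. The counts of listed genes, 3326 in all with 1646 higher and 1680 lower, moved with the threshold. They were 1593, 765 and 828 at an adjusted p below 0.001, 989, 490 and 499 with a Bonferroni correction, 996, 757 and 239 at a log2 ratio of at least 1 in size, and 566, 405 and 161 in a test against a 1.5-fold change, where fewer genes can pass by construction. An adjusted p below 0.01 or a mean normalized count of at least 10 or 50 moved no count by over 1.5 times. Shifting all log2 ratios by 0.1, in place of another scaling, left 1104 lower genes in one direction and 1204 higher genes in the other, counting only losses among listed genes. The fall of dom, -0.58, passed at 0.01 and 0.001 but not against a 1.5-fold change (adjusted p = 1). Of the 141 genes tabulated by the naming rule, 118 passed at 0.01, 95 at 0.001 and 47 against a 1.5-fold change, with directions fixed by construction.

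The direction of ribosomal protein genes kept its side of the threshold under all alternatives, with 0.0022 when draws were matched on exon length too. Adjusted p-values that passed under an alternative only were, for type II lineage genes, 0.0447 at a mean normalized count of at least 50 and 0.0029 by abundance-matched permutation (0.0115 with exon length), and for the Notch list 0.0312 at 0.01, 0.0321 at a mean of at least 50 and 0.0011 by that permutation (0.0022 with exon length). They were 0.0312 at 0.01 and 0.0277 and 0.0366 with the shifts for chromatin remodellers, 0.0277 with the upward shift for neuron markers and 0.0401 by permutation (0.0044 with exon length) for adhesion genes. Chromatin remodellers and neuron markers did not pass the draws matched on abundance and exon length. Chromatin remodellers had 1 higher gene of 12 against 2.64 in these draws (permutation, adjusted p = 0.469). Neuron markers had 0 of 7 against 1.36 (permutation, adjusted p = 0.507). The share of optic lobe genes listed lost its call at 0.01 (adjusted p = 0.0998). The cause was not tested in any of these. What depth limits is unknown, since no depths per library were used here.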

Other observations

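All tests in this part were chosen after the results were seen. Germline genes were not among the lists fixed beforehand. Of 28 germline and piRNA pathway genes 13 were listed, 9 higher and 4 lower, and all 13 passed when adjusted over the list alone. Their log2 ratios in the authors' deposited table included 4.34 for nanos, 1.99 for AGO3, 1.59 for piwi, 1.39 for BoYb, 1.23 for spn-E and 1.21 for krimp, against -0.71 for tud and -0.60 for del. Of 30 genes of testis meiotic arrest and spermatids 10 were listed, 8 higher and 2 lower, among them Taf12L at 1.42 and can at 1.04 in the authors' deposited table. Neither list differed in direction from listed genes of the same abundance, which gave 7.77 and 7.39 higher genes (permutation, adjusted p = 0.715 for both, over 2 lists). The share listed did not pass either (hypergeometric test, adjusted p = 0.0580 and 0.321).

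Other genes stood out by their values, all chosen after these were seen. The pair-rule gene ftz was 12.3-fold higher, the peroxidase gene Pxt 14.9-fold higher and the mucin gene Muc14A 10.4-fold higher in the knockdown in the authors' deposited table. The replacement histone gene His3.3B was higher at a log2 ratio of 0.58 (SE 0.12) in the authors' deposited table, beside His2Av. All 9 listed genes of the Y chromosome were higher, where listed genes of the same abundance gave 8.31 (permutation, adjusted p = 0.691 over 13 classes of biotype and chromosome). Of 41 listed genes of chromosome 4, 15 were higher, where listed genes of the same abundance gave 18.5 (permutation, adjusted p = 0.533). Among genes with a mean normalized count of at least 2000, the median exon length was 2451 bp for higher and 3906 bp for lower genes, with a Spearman rho across genes of -0.18, and of -0.14 without ribosomal protein genes. The gene cv-2 lies 13168 bp from the end of dom, and of the 6 genes listed within 100 kb of dom, cv-2 included, 3 were higher and 3 lower. Among them were Sdc at a log2 ratio of 0.41, CG9485 at -0.45 and eEFSec at -0.50 in the authors' deposited table.

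Strongly higher genes lay beside each other, with 64 neighbouring pairs at most 10 kb apart among 300 listed genes at least 4-fold higher, including Arc1 with CR10102, CR10102 with Arc2, TrxT with dhd, dhd with CG15930, CG33509 with ppk13, lncRNA:CR45517 with CG15784, and Gr59c with Gr59d. Several pairs fell in the same stretch, as from Grl40a to Ir40a (2L:22037860-22214376) and from CG9876 to lncRNA:CR44781 (2R:23090100-23111177). Pairs are therefore not separate events, and the clustering was not spread evenly over the genome. Chance placement was argued against, since 2000 draws of higher genes of the same abundance gave 31.4 pairs on average and 47 at most (share of draws 5e-04, the smallest they can give). Lower genes clustered too, with 6 pairs among 46 genes at least 4-fold lower against 0.83 in draws (share 0.001) and 28 among 239 at least 2-fold lower against 19.4 (share 0.02). Transcripts running from 1 gene of a pair into the other may account for part of the 51 pairs that do not diverge, which need read positions. By orientation they cannot link the 13 diverging, non-overlapping pairs, against 7.99 in draws (share 0.023). At 8-fold there were 2 such pairs against 1.41 in draws (share 0.413). Some diverging pairs lie within longer runs, and a transcript of a further gene crossing both members was not examined. Transcripts running on are therefore not excluded for these pairs either. Reads shared within gene families could not be told apart from separate changes. The symbols of 8 pairs began with the same letters, a rough measure that leaves out SkpC with SkpE and is not a count of families. Differences between the parental lines and shared regulation through Domino stay open and untested.

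The excess of rare transcripts among higher genes was set against gene length and an even background in the knockdown libraries, such as genomic DNA, which could add reads to every gene. Gene length gave a Spearman rho of -0.085 across genes below a mean of 100, so direction followed length little among rare genes. Rare genes were shorter than abundant ones, with median exon lengths of 1279 bp (higher) and 1341 bp (lower). At a mean of at least 2000 the medians were 2451 and 3906 bp. The rho within rare genes therefore cannot tell how much length adds to the contrast of rare and abundant genes. Assuming ratios that were not shrunken, the 420 higher genes with a mean below 50 gained a median of 16.4 normalized counts per kb of exon. The lowest 10% gained under 5.53 and the highest 10% above 45.9. Limits that were wide by construction, the upper one without subtracting the control level, left 83.1% of the 420 in reach of a common gain of 14.9. That level was picked because it lay within most limits, so this share decides nothing. Among lower genes with an implied knockdown level of at least 10, 1 gene, dtr, had its upper 95% limit under 5.53, and 7 genes did without that level, among them CG18853, most of them near the floor and too few to exclude background. Background, a part played by gene length, a difference in depth between the genotypes and a loss of repression by Domino all stay open.

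Listed neuron markers were lower, and a smaller share of neurons among the sorted cells is a candidate explanation. It stays open for Syt1, fne, cpx, Gad1, unc-13 and nrv3, because 13 of the 20 neuron markers, among them elav, nSyb and brp, were not listed and have no ratio, so whether all fell by a common factor could not be tested. The ratios of these 6 agreed within their errors (heterogeneity Q 2.79, chi-square p = 0.732), as a common factor would give, but they were selected by passing the threshold and Rbp9 was set aside after it was seen, so this decides nothing. Rbp9 differed from the weighted mean of the other 6 listed markers, -0.61 (SE 0.07), by -12.6 standard errors. A smaller share alone would not give this if Rbp9 and these markers were confined to the same neurons. That was not examined, so a smaller share is not excluded for Rbp9 either, and a change of expression within neurons was not tested. The listed hemocyte markers (4 of 12) were lower, although a sort for insc-driven GFP should leave hemocytes out. The listed glia markers (4 of 17) were higher, and whether the labelled progeny included glia was not examined.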
